A study of Candida albicans and Mus musculus with 18 samples.

How the data were processed

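The series holds 18 poly(A) 3′-end libraries (PAT-seq, single reads of 150 bases) of Candida albicans SC5314 and mouse bone-marrow-derived macrophages, grown apart or together at 3 Candida cells to 1 macrophage. Per the labels' protocols, cocultures were lysed in Trizol and spun into a fungal pellet and a macrophage supernatant, RNA was extracted separately from each (hot phenol for the pellet) and the fractions were pooled before library preparation. Groups were Candida alone, macrophages alone and coculture at time points 1, 6 and 9, with 2 libraries each, 1 per independent experiment (numbers 1 and 3, read from the sample titles).

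The authors deposited, for each organism, raw read counts per gene in all 18 libraries, the mean poly(A) tail length per gene and library in nucleotides, and the counts of reads behind each tail length, none of them normalised. Bowtie and Bowtie2 were used per the submitters' processing notes, which give no version or role. The genome builds, annotation, counting program and filters are not given in the sources used here. The values were checked: counts were whole numbers, tail read counts never exceeded the count of the same gene, and tail lengths were missing where no tail read was listed. The mouse table has 45084 features, of which 43977 hold 1 gene and 1107 join several overlapping genes; the joint features held 17.2% of mouse counts and were kept under their joint names. Of the 1-gene features, 43491 matched GENCODE M21, which gave symbols and gene types, and 486 did not. The 6214 Candida genes carry systematic identifiers without names, so the 17 Candida pathway lists and the Candida key genes fixed in advance were not used here.

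Library totals are given with the results. Shares of counts per library have exact 95% Clopper-Pearson intervals, and where a group held no count, folds were computed against a floor of 3 counts over the group. Intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules.

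Counts were analysed in R 4.3.3 with edgeR 4.0.16: TMM factors, filterByExpr by group, and quasi-likelihood F tests with 1 coefficient per group in 1 fit of the 12 libraries that hold an organism's RNA, Candida and mouse apart. After the filter 5693 Candida and 11392 mouse genes were tested. p values were adjusted by Benjamini-Hochberg over the genes tested, at a threshold of 0.05 with no fold threshold, and the SE of a log2 fold change is its size divided by the square root of F. Comparisons were coculture against single culture at each time, the difference of that effect between times 9 and 1, and changes between times within coculture and within single culture. Values in CPM, computed here with the TMM factors except for sums over cell type markers, are means with the SD of 2 libraries. Comparisons of coculture with single culture at different times share no library. They do share the experiments and the fit's spread per gene, so numbers expected for independent lists are only a reference.

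Mouse gene lists (25, of which 20 had at least 3 tested genes) were tested with camera of limma 3.58.1 at a preset correlation of 0.01, adjusted over all lists and the 3 coculture comparisons, and over the lists alone for the difference of effects; the calls were repeated with the correlation estimated from the data. Tail lengths were tested with limma on the log2 mean tail length, for genes with at least 10 tail reads in all 4 libraries compared. Named genes were, for each coculture comparison, up to 8 largest rises and falls past the threshold with a mean of at least 20 counts, the same sign in both experiments and a gene name, up to 4 members with the smallest p from each list, and a fixed set of key genes, and up to 4 rises and falls and the key genes for the other comparisons. The tests, lists, naming rule and alternatives were chosen before the data were examined, except where stated.

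The experiment numbers pair the libraries: deviations from the group means correlated within an experiment in all 15 pairs of groups, at 0.104 to 0.337 for Candida and 0.218 to 0.547 for mouse, so each test was repeated with the experiment number as an additive term. Other alternatives were RLE factors, scaling by total counts alone, no filter, DESeq2 1.42.0, a fit of only the groups compared, each library left out in turn and, for tails, at least 30 tail reads, lengths in nucleotides and weights by tail reads. A library left out leaves its group with 1, which the fit assumes to vary like the other groups. The list tests were not rerun with DESeq2, with only the groups compared or with a library left out. Subtraction of the other organism's background, measured in the single-culture library of the same experiment and time, was added after the data were seen. It used raw counts without scaling for depth, so where the single-culture library was the deeper one it could take out too much. Outlying libraries and regroupings of the samples were not tested, since the rules set for both need groups of more than 2.

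The scripts were tested on simulated counts drawn from the real means and library sizes with 200 changed genes. Each gene had 1 mean for all groups, and no experiment effect was simulated for counts or tails. The rates that follow therefore need not hold for the real calls. At 2-, 4- and 8-fold changes they recovered 25.4%, 88.1% and 98.5% of changed Candida genes at time 1, 38.8%, 92.5% and 97.0% at time 6 and 46.3%, 95.5% and 100% at time 9. For mouse genes they recovered 4.48%, 76.1% and 86.4% at time 1, 8.96%, 58.2% and 86.4% at time 6 and 4.48%, 58.2% and 86.4% at time 9. Of the calls, 1.94% to 5.93% were false. For tails, simulated log2 changes of 0.3, 0.6 and 1 were recovered for 19.4%, 83.6% and 97.0% of changed Candida genes at time 1, 14.9%, 73.1% and 92.4% at time 6 and 14.9%, 62.7% and 92.4% at time 9. For mouse genes these were 8.96%, 53.7% and 75.8% at time 1, 4.48%, 46.3% and 72.7% at time 6 and 8.96%, 44.8% and 87.9% at time 9. Of the tail calls, 1.05% to 7.07% were false. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 did the rest.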

Results

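Poly(A)-primed 3′-end sequencing measured RNA of the fungus Candida albicans (strain SC5314) and of mouse bone-marrow-derived macrophages, grown apart or together. The 18 libraries form 9 groups of 2, with Candida alone, macrophages alone and the coculture each sampled at time points 1, 6 and 9, whose unit the labels do not give. Each group holds 1 library from each of 2 independent experiments, numbered 1 and 3. Candida-alone libraries held 3037073 to 10115883 counts on Candida genes, and macrophages-alone libraries held 2955046 to 12749871 counts on mouse genes. Coculture libraries held 371614 to 5222491 Candida counts and 1106150 to 5220293 mouse counts.

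Candida genes took a growing share of the coculture libraries over time. They held 14.1% ± 2.55 (SD, n = 2) of all counts at time 1, 50.5% ± 5.90 (SD, n = 2) at time 6 and 70.0% ± 1.38 (SD, n = 2) at time 9. The exact 95% binomial interval, which covers counting error only, was 15.87% to 15.93% for experiment 1 at time 1 and 12.26% to 12.33% for experiment 3. The rise between time points was larger than the spread between experiments. Candida genes also took 0.171% to 1.41% of the counts in macrophages-alone libraries, and mouse genes took 0.449% to 3.78% of the counts in Candida-alone libraries. The fungal and macrophage RNA were extracted separately and pooled before library preparation, so these shares are not shares of cells or of RNA in the culture.

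**Figure D1:**
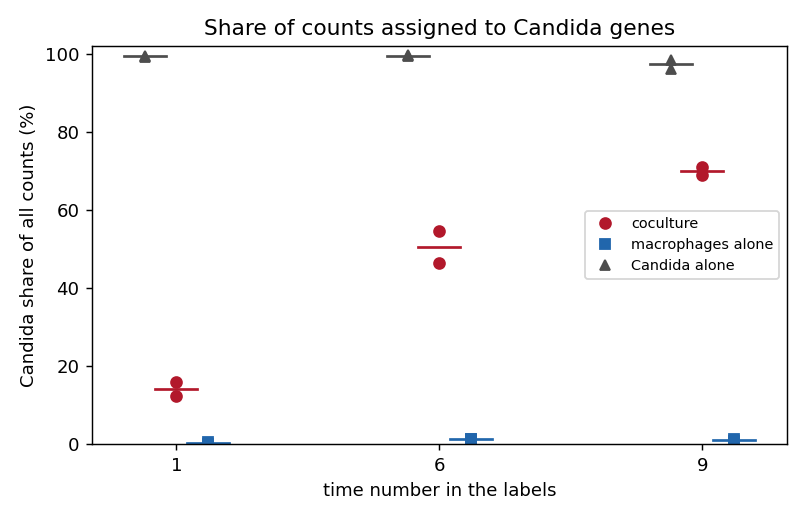
Percent of counts on Candida genes (vertical axis) against the time point number (horizontal axis), for coculture, macrophages alone and Candida alone. Points are single libraries and lines the mean of the 2 experiments. The coculture mean rose from 14.1% at time 1 to 50.5% at time 6 and 70.0% at time 9.

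The comparison of cocultured with uninfected macrophages at time 1 addressed the early response of the host cell. Genes of the NF-kB inflammatory response were higher as a group in coculture, with a median log2 fold change of 1.29 over 22 measured members (camera adjusted p = 1.1e-40, and adjusted p = 0.0225 with an estimated correlation). Cxcl2, a chemokine that attracts neutrophils, had a log2 fold change of 3.33 ± 0.60 (SE, n = 2 per group), and Nfkbia, the inhibitor that limits NF-kB, had one of 1.58 ± 0.29. The cytokine gene Tnf had a log2 fold change of 1.43 ± 0.34, and the transcription factor gene Junb one of 1.43 ± 0.23. Il1b, which encodes a pyrogenic cytokine, had 30 counts in coculture against 3 alone, a ratio of 28.4 with a counting interval of 8.84 to 146. The glucose transporter gene Slc2a1 had a log2 fold change of -0.02 ± 0.24.

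No single mouse gene passed the test at time 1 in edgeR's quasi-likelihood fit, where 111 of 11392 genes had an unadjusted p under 0.05 and DESeq2 called 5 genes, all higher. These 111 genes are a smaller share than the 0.05 expected if no gene changed. The fit without the experiment was thus conservative here, and its 0 calls do not show absence of change. With the experiment as a term in the edgeR fit, 15 genes passed, all higher: Ccl4, Nfkbia, Cd83, Plk2, Acod1, Tnf, Gm13787, Gm13771, Cebpb, Csf1, Cxcl2, Clec4e, Junb, Icam1 and Ccrl2, of which those outside the fixed lists were named after their values were seen. Without the coculture library of time 1 from experiment 1, 1 gene passed in the fit without that term. Of the NF-kB list, 14 members passed when adjusted over the list alone, against 0 over all genes. The immediate early list, genes that respond within minutes to a stimulus, was higher too (median 0.36, 18 genes, camera adjusted p = 2.31e-08, and adjusted p = 0.0295 with an estimated correlation). The integrated stress response list (median 0.22, 15 genes, camera adjusted p = 0.00229) and the list of NRF2 antioxidant genes (median 0.20, 10 genes, camera adjusted p = 0.0438) were higher by smaller amounts. Mitochondrially encoded transcripts were lower as a list (median -0.16, 30 genes, camera adjusted p = 0.0101). These last 3 calls did not hold with an estimated correlation (adjusted p = 0.201, adjusted p = 0.176 and adjusted p = 0.446), and the NRF2 call also ended by total counts (camera adjusted p = 0.0534) and without a filter (0.0703). The lysosome list was called as well with the experiment as a term (camera adjusted p = 0.0438).

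At time 6 inflammatory, interferon and hypoxia genes were higher as lists in cocultured macrophages. The glycolysis and glucose uptake list was called too, but not with an estimated correlation (adjusted p = 0.0603), and 4 of its 24 members rose. Slc2a1, the main glucose transporter of activated macrophages, rose from 85.2 ± 7.38 CPM alone to 662 ± 58.7 CPM in coculture (counts scaled to library size; SD, n = 2), a log2 fold change of 2.96 ± 0.26 (SE). Isg15, an interferon-induced ubiquitin-like modifier, rose by 4.15 ± 0.37 on the log2 scale and the antiviral gene Ifit3 by 5.04 ± 0.56. Cxcl2 rose by 6.63 ± 0.74 on the log2 scale, and Hilpda, a lipid droplet protein induced by low oxygen, by 4.01 ± 0.40. Inhba, a subunit of the cytokine activin A, had no count alone and was at least 64.5-fold higher in coculture, against a floor of 3 counts over the group. In edgeR's quasi-likelihood test, 274 genes were higher and 83 lower.

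The lists fixed in advance place these genes at time 6. Of 30 interferon response genes, 21 rose, or 28 adjusted over the list alone (median log2 fold change 3.16, camera adjusted p = 1.22e-55). Stat2, a signal transducer of the interferon receptor, stood at 2.63 ± 0.30 and Ifi204, a DNA sensor, at 2.43 ± 0.24. Of 22 NF-kB genes, 14 rose, or 19 adjusted over the list alone (median 2.65, camera adjusted p = 3.22e-27). Relb, an NF-kB subunit, was among them at 3.01 ± 0.44. Of 18 immediate early genes, 8 rose, or 13 adjusted over the list alone (median 2.20, camera adjusted p = 3.71e-21). They included Junb at 2.95 ± 0.25, Atf3, a stress-induced repressor, at 2.10 ± 0.22 and the phosphatase gene Dusp1 at 3.85 ± 0.48. Of 19 hypoxia genes, 10 rose, or 16 adjusted over the list alone (median 1.76, camera adjusted p = 4.42e-26). Examples were Bnip3, which marks mitochondria for removal, at 3.18 ± 0.39, the oxidoreductase gene Ero1l at 2.70 ± 0.34 and Egln3, an oxygen-sensing hydroxylase, at 2.62 ± 0.34. These 4 calls held with an estimated correlation (adjusted p = 0.0209, adjusted p = 0.0349, adjusted p = 0.00867 and adjusted p = 0.00867).

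Glycolysis and glucose uptake genes were higher at time 6 as a list of 24 (median log2 fold change 0.66, camera adjusted p = 3.22e-09), a call lost with an estimated correlation (adjusted p = 0.0603). Members past the test over all genes numbered 4, against 13 adjusted over the list alone: Slc2a1, the lactate exporter Slc16a3 at 1.49 ± 0.23, the hexokinase Hk1 at 1.55 ± 0.26 and the phosphofructokinase Pfkl at 1.09 ± 0.25. The lactate dehydrogenase gene Ldha had a value of 0.89 ± 0.25 (edgeR adjusted p = 0.079, and 0.00034 with the experiment as a term), and Pfkfb3, a driver of glycolytic flux, had 1.95 ± 0.71 (edgeR adjusted p = 0.21, and 3.2e-05 with that term). Txnip, which restrains glucose uptake, did not pass (-0.34 ± 0.28). The pentose phosphate list (7 genes) and the TCA cycle and respiration list (30 genes) were not called. The integrated stress response was higher (15 genes, 6 rose, 8 adjusted over the list alone, median 0.93, camera adjusted p = 6.86e-08, and adjusted p = 0.0488 with an estimated correlation). It included its transcription factor Atf4 at 1.87 ± 0.38 and the cystine transporter Slc7a11 at 3.62 ± 0.67. The NRF2 list was higher (10 genes, 2 rose, 4 adjusted over the list alone, median 0.89, camera adjusted p = 1.38e-05, and adjusted p = 0.0349 with an estimated correlation). It included Hmox1, which breaks down haem, at 1.75 ± 0.27.

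Lists of pattern receptor, cell death and lysosome genes showed smaller shifts at time 6, with few members past the test. The fungal recognition list was higher (12 genes, 2 rose, 5 adjusted over the list alone, median 0.69, camera adjusted p = 0.00234, and adjusted p = 0.0488 with an estimated correlation). It included Tlr2, a receptor of fungal cell wall components, at 2.51 ± 0.46 and Clec4e, the receptor Mincle, at 3.60 ± 0.82. The inflammasome and cell death list was higher (17 genes, 1 rose, 3 adjusted over the list alone, median 0.43, camera adjusted p = 0.0219). It was not called with the experiment as a term (camera adjusted p = 0.0506) or with an estimated correlation (adjusted p = 0.0974). Its risen member was Casp4, the sensor caspase of the noncanonical inflammasome, at 2.11 ± 0.34, while Nlrp3 had 1.15 ± 0.30 (edgeR adjusted p = 0.062, and 0.004 with the experiment as a term) and Casp1 had 0.50 ± 0.24. Lysosome and autophagy genes were slightly higher (26 genes, 2 rose, 3 adjusted over the list alone, median 0.20, camera adjusted p = 0.0402, and adjusted p = 0.476 with an estimated correlation). The autophagy receptor Sqstm1 rose by 1.60 ± 0.26. The alternative activation list (5 genes) was called only with the experiment as a term (camera adjusted p = 0.0461, against 0.169). The unfolded protein response, LXR target, macrophage identity, mitochondrially encoded and ribosomal protein lists were not called.

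Genes of DNA replication and cell division were lower at time 6. The cell cycle list was lower (29 genes, median -1.06, 5 fell, 15 adjusted over the list alone, camera adjusted p = 3.1e-14), a call lost with an estimated correlation (adjusted p = 0.0728). Its members included Ccne2, a cyclin of S-phase entry, at -1.93 ± 0.36 and the replication helicase subunit Mcm5 at -1.54 ± 0.31. Cholesterol biosynthesis genes were lower (20 genes, median -0.50, 1 fell, 2 adjusted over the list alone, camera adjusted p = 0.00177, and adjusted p = 0.261 with an estimated correlation). The squalene synthase Fdft1 stood at -1.39 ± 0.25. Among the other falls were Ctdspl, a phosphatase gene, at -3.11 ± 0.56 and Sesn1, a p53-induced regulator of growth signalling, at -2.47 ± 0.52. Mitochondrially encoded transcripts took 5.50% ± 1.01 (SD, n = 2) of mouse counts in coculture against 7.56% ± 1.94 alone at this time. Of 55 named genes past the test at time 6, the calls of Inhba, Cxcl2, Ifit3, Slc2a1, Junb, Atf3, Dusp1, Isg15, Ifi204, Stat2, Hilpda, Bnip3, Ero1l and Egln3 stayed whichever library was left out. The others ended without at least 1 library: 41 without the macrophages-alone library of time 6 from experiment 3 (edgeR adjusted p up to 0.392) and 30 without that of experiment 1 (up to 0.313). Some of these same calls also ended without either coculture library of time 6, and fewer without each library of times 1 and 9. The count of 357 genes was 33 and 109 without the macrophages-alone library of experiments 3 and 1 and 144 without the coculture library of experiment 3. With the experiment as a term, 751 genes were higher and 425 lower.

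At time 9 the glycolysis and glucose uptake, hypoxia and interferon lists were higher in coculture and the cell cycle list was lower. The NF-kB list was higher as well, a call lost with an estimated correlation (adjusted p = 0.0887). Slc2a1 reached 791 ± 48.0 CPM in coculture against 85.7 ± 28.1 alone (SD, n = 2), a log2 fold change of 3.21 ± 0.26 (SE). Txnip fell by 2.42 ± 0.31 on the log2 scale, from 126 ± 17.7 CPM alone to 24.0 ± 6.48 in coculture. Il1rn, the interleukin-1 receptor antagonist, rose by 6.39 ± 0.48 on the log2 scale, and F3, tissue factor of the clotting cascade, by 6.15 ± 0.98. Id1, an inhibitor of differentiation factors, fell by 4.13 ± 0.35, and the mitotic kinase gene Cdk1 fell by 2.55 ± 0.32. In edgeR's quasi-likelihood test, 483 genes were higher and 309 lower. Of the genes called at time 6, 226 were higher and 61 lower at time 9 too, against 11.6 and 2.25 expected for independent lists, with 0 called in opposite directions. With the experiment as a term these were 605 and 276, against 75.6 and 32.4 expected, and 2 opposite. The overlaps were not rerun with a library left out, although the calls of both times depended on single libraries.

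**Figure D2:**
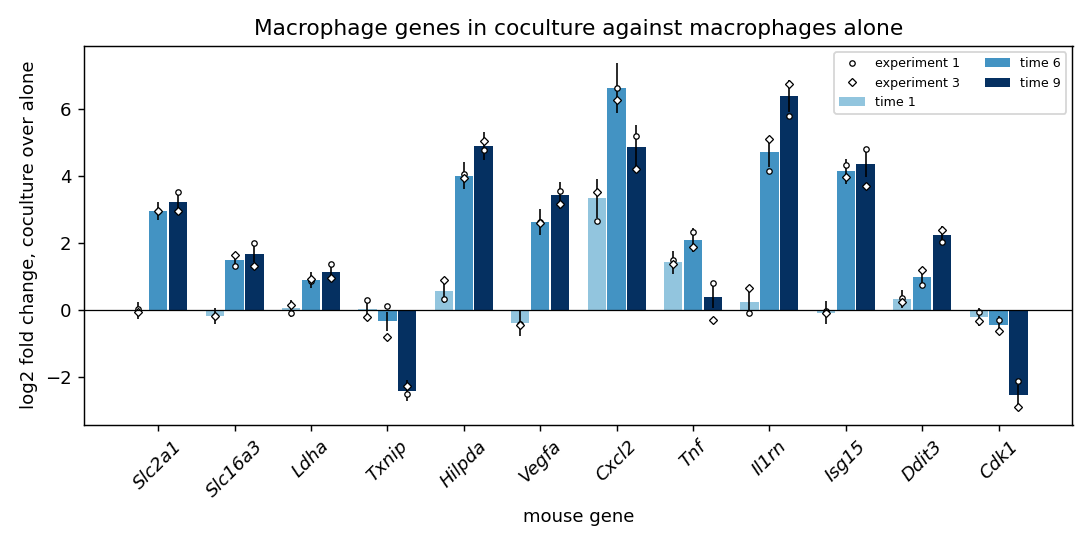
Log2 fold change of 12 mouse genes, coculture minus macrophages alone (vertical axis), at time points 1, 6 and 9; bars are the fitted values with their SE (n = 2 per group) and points the 2 experiments. The genes were picked for drawing after their values were seen; Slc2a1 was at -0.02 at time 1 and at 3.21 at time 9, and Txnip at -2.42 at time 9.

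Glycolysis genes at time 9 numbered 8 risen of 24 measured, or 17 adjusted over the list alone (median log2 fold change 1.02, camera adjusted p = 6.52e-11, and adjusted p = 0.0488 with an estimated correlation). Beside Slc2a1 they included Hk1 at 2.09 ± 0.26, Slc16a3 at 1.67 ± 0.23, Ldha at 1.14 ± 0.25 and the triose phosphate isomerase Tpi1 at 1.12 ± 0.23. The hexokinase gene Hk2 had a value of 2.20 ± 0.88 (edgeR adjusted p = 0.17, and 2.3e-07 with the experiment as a term) and Pfkfb3 had 2.18 ± 0.72 (edgeR adjusted p = 0.095, and 2.7e-05 with that term). Of 19 hypoxia genes, 12 rose, or 16 adjusted over the list alone (median 1.72, camera adjusted p = 1.55e-23, and adjusted p = 0.00867 with an estimated correlation). Examples were Hilpda at 4.90 ± 0.42, Ero1l at 3.52 ± 0.35, the angiogenic factor Vegfa at 3.42 ± 0.41 and Ndrg1 at 3.08 ± 0.42. Hif1a, the transcription factor of this response, had 1.26 ± 0.35 (edgeR adjusted p = 0.05, and 0.0055 with the experiment as a term).

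Of 30 interferon genes, 16 rose at time 9, or 26 adjusted over the list alone (median 2.43, camera adjusted p = 8.38e-26, and adjusted p = 0.0488 with an estimated correlation). Isg15 stood at 4.36 ± 0.38 and Ifit2 at 4.56 ± 0.60. Of 22 NF-kB genes, 12 rose, or 17 adjusted over the list alone (median 2.07, camera adjusted p = 4.03e-14), a call lost with an estimated correlation (adjusted p = 0.0887). Cxcl2 stood at 4.85 ± 0.68 and the mitochondrial superoxide dismutase Sod2 at 1.88 ± 0.30, while Tnf did not pass (0.39 ± 0.35). Of 18 immediate early genes, 9 rose and 1 fell, or 12 and 1 adjusted over the list alone (median 2.30, camera adjusted p = 5.91e-13, and adjusted p = 0.0209 with an estimated correlation). Atf3 stood at 2.90 ± 0.23 and the transcription factor Egr2 at 4.46 ± 0.71. Integrated stress response genes rose in 7 of 15, or 9 with 1 lower adjusted over the list alone (median 0.77, camera adjusted p = 2.84e-08, and adjusted p = 0.0488 with an estimated correlation). They included the asparagine synthetase Asns at 1.88 ± 0.24, Slc7a11 at 5.23 ± 0.77 and Ddit3, the pro-apoptotic factor CHOP, at 2.22 ± 0.30. The NRF2 list (10 genes, 1 rose, 3 adjusted over the list alone, median 0.85, camera adjusted p = 0.0176) and the lysosome list (26 genes, 2 rose, 2 adjusted over the list alone, median 0.43, camera adjusted p = 0.0028) were higher too. Both calls were lost with an estimated correlation (adjusted p = 0.106 and adjusted p = 0.283).

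Of 29 cell cycle genes, 18 fell at time 9, or 26 adjusted over the list alone (median -1.73, camera adjusted p = 6.98e-22, and adjusted p = 0.0488 with an estimated correlation). Cdc20, an activator of the anaphase-promoting complex, stood at -3.43 ± 0.52 and Mcm5 at -2.14 ± 0.33. E2f8, a repressor of E2F target genes, had no count in coculture and was at least 11.0-fold lower. Skp2, a ubiquitin ligase subunit that degrades cell cycle inhibitors, was at least 9.56-fold lower. Cholesterol genes were lower (20 genes, 1 fell, median -0.52, camera adjusted p = 0.0175, and adjusted p = 0.388 with an estimated correlation), again with Fdft1 past the test (-1.54 ± 0.26). The mitochondrially encoded list was not called (camera adjusted p = 0.556, but 0.0353 and lower after background subtraction), yet these transcripts took 4.15% ± 0.200 (SD, n = 2) of mouse counts in coculture against 8.17% ± 0.263 alone. Among them mt-Nd3, a subunit of respiratory complex I, fell by 2.14 ± 0.36 on the log2 scale. That call ended without the coculture library of time 9 from experiment 3, and the median of the 30 list members was -0.01. The fungal recognition list (camera adjusted p = 0.0661) and the ribosomal protein list (camera adjusted p = 0.0661) were called with the experiment as a term (camera adjusted p = 0.00756 and 0.0116), and the ribosomal protein list also without a filter on low counts (0.0184). The ribosomal protein list was matched by symbol and also took in S6 kinase genes: its members past the test, Rps6ka1 (-1.34 ± 0.30) and Rps6ka2 (2.00 ± 0.51), encode such kinases and no ribosomal protein. The inflammasome, pentose phosphate, TCA cycle, unfolded protein, LXR, alternative activation and macrophage identity lists were not called, although the TCA cycle list was called lower without a filter (camera adjusted p = 0.00947). A list that was not called could still hold changed genes. Arg1, Tgm2, Casp4, Cd14, Tlr2 and Clec4e each passed the test over all genes at this time. Their calls, except that of Cd14, depended on single libraries. For alternative activation (median -0.18) and macrophage identity (median -0.10) the median was negative and the test pointed up.

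Markers of other cell types stayed low in the mouse libraries. The 11 macrophage identity genes summed to 11019 to 12750 CPM in the 6 groups, and 10 neutrophil markers summed to 5.78 ± 3.06 in coculture at time 9 against 15.8 ± 6.43 alone (SD, n = 2). Lymphocyte, dendritic, stromal, and erythroid and mast cell markers summed to at most 4.15, 0.453, 2.17 and 0.0784 CPM in any group, and with fewer than 3 tested genes each these lists, like the neutrophil list, had no set test after the filter on low counts.

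At time 9, 38 of 63 named genes past the test kept their call whichever library was left out. Among these were Slc2a1, Txnip, Il1rn, F3, Id1, Cdk1, Hk1, Slc16a3, Hilpda, Vegfa, Isg15, Cxcl2, Atf3, Asns, Ddit3, Slc7a11, Cdc20, Mcm5 and Fdft1, while Ldha and Tpi1 were not. Leaving out the macrophages-alone library of time 9 from experiment 3 ended 23 calls (edgeR adjusted p up to 0.244) and that of experiment 1 ended 16 (up to 0.153), while either coculture library of time 9 ended 17 (up to 0.246 for experiment 1 and 0.159 for experiment 3). At most 3 calls ended without each library of times 1 and 6 (edgeR adjusted p up to 0.0581). The count of 792 genes was 178 and 315 without the macrophages-alone library of experiments 3 and 1, and 345 and 388 without the coculture library of experiments 3 and 1. An edgeR fit with the experiment as a term gave 1147 genes higher and 869 lower. Mouse counts of the Candida-alone libraries, not scaled for depth, amounted to 5.12% and 10.8% of the coculture counts of experiments 1 and 3 at this time. Scaled by total counts alone the median of all genes was -0.19, against -0.03, and 332 genes were higher and 381 lower.

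**Figure D3:**
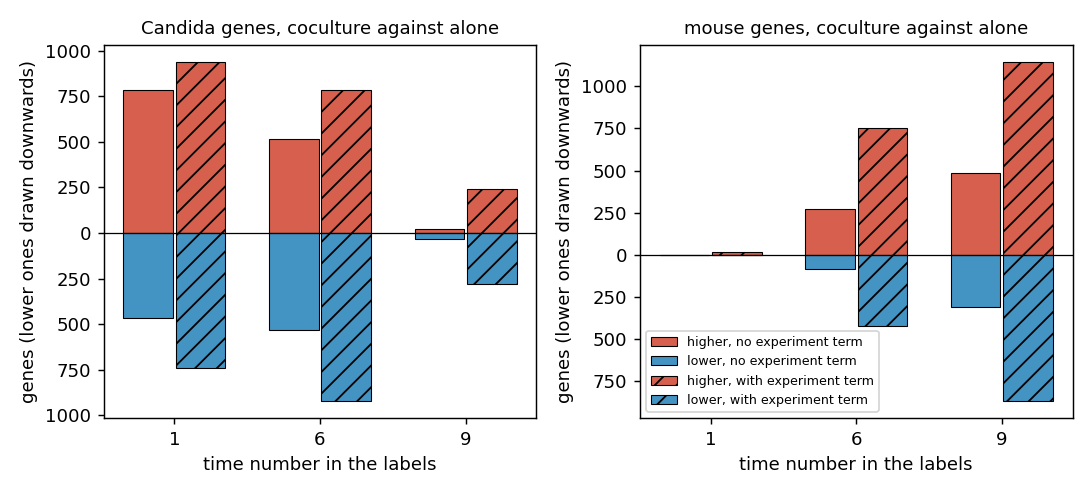
Number of genes called higher (above 0) and lower (below 0) in coculture than alone at time points 1, 6 and 9, for Candida and mouse, without and with the experiment as a term in the edgeR fit. Without the term, mouse calls numbered 0 at time 1 and 792 at time 9, and Candida calls 1251 at time 1 and 58 at time 9.

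The difference between the coculture effects at times 9 and 1 was tested to ask which host responses changed as the infection went on. Slc2a1 had an effect larger at time 9 by 3.23 ± 0.35 on the log2 scale (edgeR adjusted p = 0.0036), and Il1rn by 6.17 ± 0.58 (edgeR adjusted p = 0.0018). The effect on Txnip was more negative by -2.46 ± 0.41, that on Id1 by -3.36 ± 0.43 and that on Slc16a3 more positive by 1.85 ± 0.32. Of 20 lists, 9 differed. The effect was larger for interferon genes by a median of 2.49 (camera adjusted p = 2.16e-29), hypoxia genes by 1.58 (camera adjusted p = 2.18e-18), immediate early genes by 1.55 (camera adjusted p = 9.64e-08), glycolysis genes by 0.90 (camera adjusted p = 1.12e-10), and integrated stress genes by 1.12 (camera adjusted p = 1.18e-05). It was larger for NF-kB genes by 0.78 (camera adjusted p = 0.0116) and lysosome genes by 0.36 (camera adjusted p = 0.025), and lower for cholesterol genes by -0.56 (camera adjusted p = 0.00649) and cell cycle genes by -1.97 (camera adjusted p = 6.85e-23). With an estimated correlation the integrated stress (adjusted p = 0.0846), NF-kB (adjusted p = 0.508), lysosome (adjusted p = 0.362) and cholesterol (adjusted p = 0.245) calls were lost. With the experiment as a term, the NRF2 (camera adjusted p = 0.0424), alternative activation (0.0348), fungal recognition (0.0348) and ribosomal protein (0.0376) lists were called too. Without a filter the fungal recognition (camera adjusted p = 0.0477), ribosomal protein (0.0372) and TCA cycle (0.0341, lower) lists were called.

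In this test 53 genes had a higher and 18 a lower effect at time 9 in edgeR, 470 and 313 with the experiment as a term. By total counts alone the median of all genes was -0.19, against -0.03, and the numbers were 27 and 18. The count of 71 rested on each library of times 1 and 9. Without the macrophages-alone library of time 9 it was 13 for experiment 1 and 7 for experiment 3, and without the coculture library of time 9 it was 16 and 9. Without the macrophages-alone library of time 1 it was 17 for either experiment, without the coculture library of time 1 it was 21 and 13, and without the macrophages-alone library of time 6 it was 47 and 42. Of the 11 named genes past the test, Slc2a1 and Il1rn kept the call whichever library was left out. Id1 lost it without the coculture library of time 9 from experiment 1 (edgeR adjusted p = 0.0516). Txnip and Slc16a3 lost it without any 1 of several libraries, mostly of times 1 and 9. Their highest edgeR adjusted p were 0.0990 for Txnip, without the macrophages-alone library of time 9 from experiment 3, and 0.118 for Slc16a3, without that of experiment 1.

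Over time within the coculture, macrophage Slc2a1 rose from time 1 to time 6 by 3.13 ± 0.26 on the log2 scale, and Slc16a3 by 1.74 ± 0.23 (SE, n = 2 per group). The antiviral genes Ifit2 and Ifit3 rose by 4.33 ± 0.56 and 4.13 ± 0.54 and Mcm5 fell by 1.95 ± 0.31. Across these times, 74 mouse genes were higher and 20 lower in edgeR, 474 and 248 with the experiment as a term. The 94 genes became 6 and 23 without the coculture library of time 1 from experiments 1 and 3 and 39 without that of time 6 from experiment 3. Of 10 named genes past the test, Slc2a1 alone kept its call whichever library was left out, and without the coculture library of time 1 from experiment 1 the other 9 lost theirs (edgeR adjusted p 0.0675 to 0.233). From time 6 to time 9 in coculture 0 mouse genes passed in edgeR, with 684 at an unadjusted p under 0.05, 18 called by DESeq2 and 39 by edgeR with the experiment as a term. Txnip had the value -2.04 ± 0.31 there and Slc2a1 0.26 ± 0.24. In macrophages alone 0 genes passed in edgeR from time 1 to 6 (238 at an unadjusted p under 0.05, 6 by DESeq2, 15 with the experiment as a term) or from time 6 to 9 (91 at an unadjusted p under 0.05, 0 by DESeq2 and 0 with that term). Slc2a1 had log2 changes of 0.15 ± 0.24 and 0.00 ± 0.24 in macrophages alone.

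For Candida the same comparison asked how the fungus responds to macrophages. At time 1, 782 Candida genes were higher and 469 lower in coculture than alone in edgeR's quasi-likelihood test, of 5693 tested. The gene orf19.7111.1 rose from 28.8 ± 12.1 to 2913 ± 534 CPM (SD, n = 2), a log2 fold change of 6.65 ± 0.85 (SE), and orf19.3112 rose from 0.952 ± 0.350 to 25.3 ± 2.57 CPM, a log2 fold change of 4.71 ± 0.74. Both kept their call whichever library was left out. The files name Candida genes by systematic identifier only and pair none with a name, so the 17 Candida pathway lists could not be tested, and these identifiers were chosen after their values were seen. The coculture libraries of time 1 stood apart on the second principal component of the Candida data (29.9% of the variance), at 40.4 and 87.8 against -26.9 to -1.83 for the other 10. They also held the fewest Candida counts of the libraries in the fit, 986795 and 371614, so depth and coculture are not separated on this component. Candida counts of the macrophages-alone libraries, not scaled for depth, amounted to 1.54% and 16.8% of the coculture counts of experiments 1 and 3 at this time. Both macrophages-alone libraries were deeper in mouse counts (8873125 against 5220293 and 12749871 against 2651565), so these shares are larger than shares scaled to depth would be. Without the Candida-alone library of time 1 from experiment 3 the count of 1251 was 771, and without the coculture library of experiment 3 it was 806. Scaled by total counts alone, the median of all genes was 0.18, against 0.01, and 945 were higher and 303 lower.

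At time 6, 518 Candida genes were higher and 531 lower in coculture. The genes orf19.3112 and orf19.7111.1 were higher by 5.95 ± 0.65 and 4.63 ± 0.78 on the log2 scale (SE, n = 2 per group). The gene orf19.6200 was lower, at -2.30 ± 0.54. All 3 identifiers were chosen after their values were seen, among genes past the test in the same direction at times 1 and 6. Their agreement between these times was thus set by the choice and is no result. Most shared calls went the other way: 248 genes that were higher at time 1 were lower at time 6, and 216 that were lower at time 1 were higher at time 6. These 464 opposite calls stood against 116 expected for independent lists, and 50 genes were called in the same direction against 115 expected. An edgeR fit with the experiment as a term gave 777 opposite calls against 254 expected and 86 in the same direction against 249. The opposite calls were not rerun with a library left out, although the calls of time 6 depended on single libraries. Over all 5693 genes the log2 fold changes of the 2 times had a correlation of -0.110. With the experiment as a term in edgeR, 783 genes were higher and 923 lower at time 6. The count of 1049 was 310, 591, 401 and 559 without the Candida-alone library of time 6 from experiments 1 and 3 and the coculture library of time 6 from experiments 1 and 3, and orf19.6200 lost its call without the Candida-alone or the coculture library of experiment 1 (highest edgeR adjusted p 0.172). Scaled by total counts alone, the median of all genes was -0.27, against -0.11, and 412 genes were higher and 830 lower. The balance leaned the other way with RLE factors (619 higher and 435 lower), DESeq2 (758 and 535) and background subtraction (523 and 344).

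At time 9, 24 Candida genes were higher and 34 lower in edgeR, and orf19.3112 and orf19.7111.1 did not pass, with log2 fold changes of 0.03 ± 0.66 and 0.74 ± 0.67. DESeq2 called 218 higher and 159 lower, edgeR with RLE factors 25 and 24, and edgeR with the experiment as a term 242 and 278. After background subtraction, not scaled for depth, edgeR called 8 genes, 6 higher and 2 lower. The count of 58 was 0 without the coculture library of time 9 from experiment 1, 1 without the Candida-alone library of time 9 from experiment 1 and 118 without the coculture library of time 9 from experiment 3. It was 14 without the Candida-alone library of time 6 from experiment 1 or from experiment 3, and 29 and 30 without the coculture library of time 6 from experiments 1 and 3. The difference between the effects at times 9 and 1 was itself past the test for 1299 genes, 499 with a higher and 800 with a lower effect at time 9. That count was 857 without the coculture library of time 9 from experiment 1, and by total counts alone, with a median of all genes of -0.31, the numbers were 358 and 1003.

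Candida genes also changed over time in either culture. From time 1 to time 6, 1226 genes were higher and 814 lower alone, and 467 were higher and 620 lower in coculture, in edgeR; the difference between these counts was not tested. From time 6 to time 9, 79 genes were higher and 59 lower alone, and 156 were higher and 43 lower in coculture. The late counts with the experiment as a term were 466 alone and 589 in coculture. Scaled by total counts alone, the early counts alone were 1762 and 524, with a median of all genes of 0.42 against 0.13, and the late counts in coculture 276 and 30, with a median of 0.20 against 0.03. The late count in coculture also turned to 276 higher and 196 lower with DESeq2. The early count of 2040 alone was 1283 without the Candida-alone library of time 6 from experiment 1. The early count of 1087 in coculture was 581, 518 and 616 without the coculture libraries of time 6 from experiments 1 and 3 and of time 1 from experiment 3. The late count of 138 alone was 6, 8, 34 and 42 without the Candida-alone libraries of time 6 from experiments 1 and 3 and of time 9 from experiments 1 and 3, and that of 199 in coculture was 24, 57 and 25 without the coculture libraries of time 6 from experiments 1 and 3 and of time 9 from experiment 3.

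Poly(A) tails, the adenosine stretches at the 3′ end that the same reads cover, passed the test for almost no gene. Median tail lengths per library lay between 34.6 and 40.4 nucleotides for Candida genes and between 48.3 and 51.7 nucleotides for mouse genes. At time 1 limma called 1 of 3653 Candida genes, orf19.7511, singled out after its value was seen, with a mean tail of 19.1 ± 0.730 nucleotides in coculture against 31.6 ± 0.606 alone (SD, n = 2; limma adjusted p = 0.0335). That call was absent with the experiment as a term (0 genes) and without the Candida-alone library of time 1 from experiment 3 (0 genes), and without that of experiment 1 it was lost while 1 other gene had a longer tail. The count was 454 and 72 without the coculture library of time 1 from experiments 1 and 3. limma called 0 of 5095 Candida genes at time 6 (379 at an unadjusted p under 0.05) and 0 of 5316 at time 9 (407). It called 0 of 8520, 7116 and 5931 mouse genes at times 1, 6 and 9 (218, 382 and 499). Leaving out the coculture library of experiment 1 gave 1 Candida and 1 mouse call at time 6 and 31 mouse calls at time 9. Median log2 differences of tail length over genes at times 1, 6 and 9 were -0.07, 0.05 and -0.10 for Candida and 0.05, 0.03 and 0.01 for mouse.

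Positions of 6 named mouse genes, from the GENCODE M21 annotation of GRCm38, follow, since the build behind the deposited counts is not given in the sources used here. Slc2a1 lies on chromosome 4 from 119108711 to 119137983, Il1rn on chromosome 2 from 24336853 to 24351494, and Cxcl2 on chromosome 5 from 90903871 to 90905938. Txnip lies on chromosome 3 from 96557957 to 96561883, Isg15 on chromosome 4 from 156199424 to 156200818, on the minus strand, and Hilpda on chromosome 6 from 29272488 to 29275446. The annotation lists all 6 as protein-coding genes, and the other 5 lie on the plus strand.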

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

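The tests on Candida counts in macrophage libraries and on opposite Candida effects were chosen after those patterns had been seen, with the outcome that would count for or against each explanation written down before it was run, except for the slopes of the time course, where it was written after.

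Every library of macrophages alone held Candida counts, from 0.171% to 1.41% of all counts (15240 to 87406 counts). The profile of these counts over Candida genes resembled that of the Candida libraries of the other experiment, with Spearman correlations across genes of 0.699 or more, which argues against mouse reads misassigned to Candida genes, expected at 0.3 or less. The correlation reached at least 0.836 of that of a Candida profile thinned to the same total, so Candida RNA or reads carried over from Candida libraries or cultures are a candidate source. Carry-over at sequencing and fungal RNA in the culture predict the same profile and were not separated. Genes are not independent replicates, so these correlations describe the libraries.

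Candida effects of coculture were often opposite at times 1 and 6, with 464 genes called in opposite directions against 116 expected for independent lists, although over all 5693 genes the correlation of the log2 fold changes was -0.110 (-0.101 after background subtraction). The 464 opposite calls were not rerun with a library left out, although the calls of time 6 depended on single libraries. Background counts in the shallow coculture libraries of time 1 are argued against as the whole cause, since 388 opposite calls against 89.0 expected, a ratio of 4.36, were left after background subtraction. That subtraction was not scaled for depth and could take out too much. Library scaling is argued against too, since the lower ratio over the other scalings was 3.26. Whether cocultured Candida held an earlier profile at time 6 or a later one at time 1 cannot be told apart from other changes: the effect at time 6 correlated with the change from time 6 back to time 1 in Candida alone of the other experiment (Pearson 0.510 and 0.582), and that at time 1 with the change from time 1 to time 6 (0.430 and 0.513), but both differences subtract the same condition, which makes unrelated profiles correlate too. A time course in coculture that does not follow that of Candida alone is no separate explanation. Effects that change sign between times already require it for the genes concerned, so the slopes over all genes describe the pattern only. Across genes the change from time 1 to time 6 in coculture had slopes of -0.0988 and -0.0635 on that in Candida alone of the other experiment, against 0.843 and 0.921 for Candida alone, and these changes share no condition. The slopes do not say whether the time course was delayed or of another kind, and no growth measurement is available.

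Mouse genes took 0.449% to 3.78% of the counts in Candida-alone libraries, a signal outside the comparisons. The effect of coculture differed between times 9 and 1, by a test of the difference itself, for 1299 Candida genes and 71 mouse genes. It also differed for Slc2a1 (3.23), Slc16a3 (1.85) and Txnip (-2.46), as log2 differences. Among the gene lists called by camera the median differences were 0.90 for glycolysis, 0.78 for NF-kB, 1.55 for immediate early, 2.49 for interferon, 1.58 for hypoxia, 1.12 for integrated stress, -0.56 for cholesterol, 0.36 for lysosome and -1.97 for cell cycle genes. With an estimated correlation the calls of the NF-kB (adjusted p = 0.508), integrated stress (adjusted p = 0.0846), lysosome (adjusted p = 0.362) and cholesterol (adjusted p = 0.245) lists were lost.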

How the results depend on the processing

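Background subtraction and the comparison of small RNA genes were added after the data were seen. Reruns left 416 of 428 results for named genes on the same side of the threshold and in the same direction after background subtraction, 425 with RLE factors, 410 by total counts, 396 with DESeq2, 374 without a filter, 377 of 420 with only the groups compared (41 lost) and 4659 of 5136 with a library left out (340 lost). Results that changed direction were past the threshold in neither fit: 115 with a library left out, 5 by total counts, 4 without a filter, 3 with the experiment as a term, 1 with DESeq2 and 1 with only the groups compared. Mouse list calls numbered 27 of 60, 15 with an estimated correlation, 30 with the experiment as a term (4 gained, 1 lost), 28 without a filter (2 gained, 1 lost), 28 after background subtraction (1 gained), 26 by total counts (1 lost) and 27 with RLE factors. At the depth of these libraries simulated 2-fold changes were recovered for 4.48% of mouse genes at times 1 and 9; depth itself was not varied.

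Pairing by experiment, as a replicate block, gave 1706 Candida genes at time 6 (1049 without it), 520 at time 9 (58), 589 from time 6 to 9 in coculture (199) and 466 alone (138). For mouse it gave 15 genes at time 1 (0), 1176 at time 6 (357), 2016 at time 9 (792), 783 for the difference of effects (71), 722 from time 1 to 6 in coculture (94), 39 from time 6 to 9 (0) and 15 alone from time 1 to 6 (0), and for Candida tails at time 1 it gave 0 (1). It also raised Candida counts to 1681 at time 1 (1251), with 741 lower (469), 1786 for the difference (1299), with 785 higher (499), and 1569 and 2592 from time 1 to 6 in coculture and alone (1087 and 2040), with 736 higher in coculture (467). It put 71 named results past the threshold, ended no named call and moved no other total of genes called in a comparison by over 1.5 times. Overlaps of calls between times, also larger with it, are given with the results.

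Without a filter, 89 Candida genes passed at time 9 and 16, 621, 336, 324, 39, 8 and 1 mouse genes passed at time 1, at time 6, for the difference, from time 1 to 6 and 6 to 9 in coculture, and for the same steps alone. DESeq2 gave 377 Candida genes at time 9, 472 and 356 from time 6 to 9 in coculture and alone, and 5, 610, 282, 289, 18 and 6 mouse genes at time 1, at time 6, for the difference, from time 1 to 6 and 6 to 9 in coculture and from time 1 to 6 alone. Total counts gave 306 Candida genes from time 6 to 9 in coculture and 45 mouse genes for the difference. With only the groups compared, so fewer libraries, Candida counts were 794 at time 1 and 312 and 257 from time 6 to 9 in coculture and alone, and mouse counts 181 at time 6, 330 at time 9, 14 for the difference and 31 from time 1 to 6 in coculture. Background subtraction gave 8 Candida genes at time 9, 113 and 61 from time 6 to 9 in coculture and alone, and 4 mouse genes from time 6 to 9 in coculture. For tails, at least 30 reads gave 3, nucleotides 0 and weights 0 Candida genes at time 1, and weights 58 Candida and 6 mouse genes at time 9. Beyond the smaller fits, the cause was not tested.

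With 1 library left out, Candida counts ranged from 771 to 1277 at time 1, 310 to 1242 at time 6, 0 to 118 at time 9, 857 to 1299 for the difference, 518 to 1074 and 24 to 230 from time 1 to 6 and 6 to 9 in coculture, and 1283 to 2281 and 6 to 178 alone. Mouse counts ranged from 0 to 1 at time 1, 33 to 343 at time 6, 178 to 828 at time 9, 7 to 65 for the difference and 6 to 90 from time 1 to 6 in coculture, and stayed at 0 for the 3 other steps. Tail counts ranged from 0 to 454 and 0 to 1 for Candida at times 1 and 6, and 0 to 1 and 0 to 31 for mouse at times 6 and 9, with 0 for Candida at time 9 and mouse at time 1. The libraries behind these shifts are named with the results.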

Other observations

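The comparison of small non-coding RNA genes, and the tests on it, were chosen after their values were seen. Some small non-coding RNA genes, mostly small nuclear RNAs, were among the genes higher in cocultured macrophages at time 9. Rn7sk, the scaffold of a complex that holds back transcription elongation, had a log2 fold change of 5.25 ± 0.71 (SE, n = 2 per group; edgeR adjusted p = 0.0017), Rmrp, the RNA of a ribosomal RNA processing enzyme, 4.96 ± 1.06 (edgeR adjusted p = 0.017), and Rnu1a1, a U1 spliceosome RNA, 4.61 ± 1.01 (edgeR adjusted p = 0.019). Rnu11, a component of the minor spliceosome, had no count in macrophages alone and was at least 98.4-fold higher in coculture. Of 69 tested small RNA genes, 14 were higher and 0 lower: 8 of 18 small nuclear RNAs, 4 of 17 ribosomal RNAs, 1 of 5 miscellaneous RNAs, 1 of 3 ribozyme RNAs, 0 of 25 small nucleolar RNAs and 0 of 1 Cajal body RNA. This 20.3% stood against 4.14% of the 11323 other genes. A Fisher test of this difference was run but is not used, because the class was picked for its high members. Of the 14, 8 had at most 3 counts in macrophages alone, so their folds are uncertain. At time 6, 2 of 69 were higher. U1 and 5S genes come in near-identical copies that share reads, so which copy was higher is uncertain.

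Candida reads of conserved small RNAs assigned to mouse genes are argued against, since the Candida-alone libraries projected 0% of the coculture counts at the median of the 14 genes, and 5.92% at most. General RNA quality of the coculture libraries stays open: the 55 small RNA genes not called had a median log2 fold change of 0.86, between quartiles of -0.37 and 3.13, and the mitochondrially encoded share differed between these groups too. That median mixes classes. All ribosomal RNA genes not called had positive values, from 1.94 (n-R5s106) to 5.03 (n-R5s28), on few counts. Small nucleolar RNAs went both ways, on few counts and with none past the test. Those with a count in every library compared ran from -2.39 (Gm24507) to 2.45 (Gm23443). The extremes beyond these rest on empty libraries. Gm24452, the lowest, had no count in coculture against 3 and 16 alone, so its fitted value is not used. Snord37, the highest at 3.52, had 14 and 0 counts in the coculture libraries of experiments 1 and 3. Loss of poly(A) selectivity or a change in the cells could each give such values, and the design does not separate them. The count of 14 was 2 without either macrophages-alone library of time 9, 3 without either coculture library of time 9, 4 and 6 without either macrophages-alone library of time 1 and of time 6, and 7 and 8 without the coculture library of time 1 from experiments 1 and 3. It was between 10 and 25 under the other scalings, filters and terms, and 8 of 23 with only the groups compared.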
